A study of Homo sapiens with 6 samples.

How the data were processed

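Open chromatin was measured by ATAC-seq (assay for transposase-accessible chromatin with sequencing) in HG3, an established cell line of B-cell chronic lymphocytic leukaemia (CLL). Per the labels' protocols, sorted cells were permeabilised with digitonin and transposed with Tn5, the fragments were amplified by PCR, and the libraries were sequenced as read pairs on a NextSeq 500. The 6 libraries were 2 sorted populations, called high survivorship and low survivorship in the titles, at 3 numbered time points each. The names under which the lists were deposited carry CXCR4 for the high-survivorship and CD18 (the product of ITGB2) for the low-survivorship population; groups and time points were taken from the titles alone.

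The authors deposited 1 list of peaks per library, with no read counts, called per sample with MACS2 on GRCh38, per the submitters' processing notes. The version of MACS2 and its options are not given in the sources used here. The names of the deposited lists mention trimming, removal of duplicates, a Tn5 shift of the reads, a p-value limit, a limit on the number of peaks and a filter step, and nothing further describes these steps. Each list was sorted by p and numbered up to peak 300000, so that the limit on the number of peaks set the length of the lists, and the lowest −log10 p kept was 4.33 to 5.19. Each peak has a display score, which in the deposited lists equals 10 times −log10 p up to a top value. Each peak also has a fold enrichment over the local background, the −log10 of its p-value and the −log10 of its q-value, all made by the authors' peak caller within 1 library. The last column of the deposited lists is the position of the summit within the peak. These values are the authors', and they were used here only to rank and filter peaks within their own list. Because the lists hold no counts, the depth of the libraries is unknown, and no counting interval can be given.

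Peaks on chromosomes 1 to 22 and X were kept, and lines with the same interval and different summits were counted once, at the summit with the highest −log10 p. Each list was then reduced to its 75000 intervals with the highest −log10 p, and the 6 reduced lists were merged with bedtools 2.31.1 (any overlap) into 115987 union regions. A region was called group-specific when it held a kept interval in 3 of 3 libraries of one population and 0 of 3 of the other. The count of group-specific regions was compared with the same count in all 10 splits of the 6 libraries into 3 and 3.

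Ranks were taken from lists of 1 common length, 178876 intervals, the length of the shortest list of distinct intervals. A region with no peak within that length took rank 178877 in that library, so the size of a difference against such a library depends on this value. The −log2 of the best rank was compared between the populations with limma 3.58.1 in R 4.3.3 (moderated by trend and robust empirical Bayes, group as the only term) over 70482 regions found in the top 75000 of at least 3 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of single regions come from this limma test. Regions named as group-specific were chosen from the same ranks, so their adjusted p-values are not independent evidence of a difference. A log2 rank difference is given as high minus low survivorship, positive where the region ranked better in the high-survivorship libraries. It is a difference of rank within each library, not of accessibility in absolute terms.

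The time-point numbers may pair the samples. After removal of the population means, libraries with the same number correlated at r = 0.307, 0.205 and 0.199, and libraries with different numbers at −0.234 to 0.064. Deviations from a mean are tied to each other within a population, so these correlations are not independent. A fit with the time point as a replicate block was therefore run as an alternative. The time points served as the replicates of a population (3 per population). Nothing in the labels says that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. An exact test of 3 libraries against 3 cannot go below p = 0.1 two-sided, and one that exchanges labels only within time points cannot go below 0.25.

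Coordinates are those of the deposited lists, 1-based on GRCh38. Genes came from a RefSeq table of the same build with 19970 protein-coding genes, which gives the extent of each gene but neither strand nor exons, and no genome sequence was used here. The planned measures therefore changed in 2 places. A region was assigned to the nearest protein-coding gene body, in place of the nearest start site, within 100 kb (100180 regions), and the promoter share became the share of summits within 1000 bp of either end of a protein-coding gene. The planned search for transcription factor motifs was not run. Whether a region within a gene lies in an exon, an intron or a UTR is not given for the same reason.

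For each of 17 gene lists and each direction (34 tests), the number of genes with at least 1 group-specific region was compared with 10000 random lists of the same size, matched on the number of union regions per gene in 10 bins (two-sided permutation p, Benjamini-Hochberg adjustment). An exact binomial test of high-only against low-only regions of each list was a description only, since regions of 1 gene are not independent. CD20 and CLLU1, 2 names of the CLL list, matched no gene in the table. The pair of markers in the names of the lists, CXCR4 and ITGB2, was kept out of these tests. Per chromosome, group-specific regions were compared with union regions elsewhere by Fisher's exact test.

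The libraries were compared by the base-pair Jaccard index of their top 75000 intervals. Regions named in the text follow a rule: per direction, the 10 group-specific regions with the best mean rank in the population that holds them, 1 per nearest gene; the 5 best among those within 1000 bp of a gene end; per gene list and direction, the genes with the best-ranked group-specific regions, up to 4, of which the leading 1 to 3 appear in the text, with any region the rule names for the same gene in the other direction, save 1 region that is not reported here; all regions of CXCR4 and ITGB2; and chromosomes past the threshold. Gene lists, naming rule, tests and most alternatives were fixed before the data were examined; where the text says that a test was added, it was chosen afterwards.

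The rank test and the list test were tested on simulated data. Of 200 simulated regions each, shifted by 1, 2 and 4 log2 rank units among 115987, the rank test found 0.5%, 26.0% and 87.0%, while 7 of the unchanged regions were called, 2.99% of all calls. The rule of 3 of 3 against 0 of 3 found 2.0%, 11.5% and 48.5% of the same regions. It also took up 875 unchanged ones (0.758%), more than all the shifted regions it found. The shifted regions were drawn from a middle range of mean ranks. Simulated noise was normal and independent between libraries, unlike the correlated deviations of the real libraries. The 2.99% is therefore not a rate of false calls in the real data. Of 200 simulated lists with no effect, tested in both directions, 1.75% gave p under 0.05, and 100% of 20 planted lists were found. Most genes of a planted list were drawn from those with a high-only region. This does not show that a weaker gathering would be found. Alternatives covered the number of peaks kept, the definition of presence and absence, the score and filter of the rank test, the gene assignment, each library and each time point left out in turn, and the replicate block. Scripts ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.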

Results

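Chromatin accessibility was compared between 2 populations sorted from the CLL cell line HG3, termed high survivorship and low survivorship, with 3 libraries each at time points 1, 2 and 3. The series concerns clonal dynamics followed by barcoding, and the comparison asks where open chromatin differs between the populations and whether that difference exceeds the one between time points. Each deposited list held 299509 to 299726 peaks. After peaks with the same interval were joined, 212306, 178876 and 198867 intervals remained in high-survivorship libraries 1 to 3, and 204526, 184539 and 191342 in low-survivorship libraries 1 to 3. At rank 75000, the last one kept, −log10 p was 7.67, 11.4 and 8.49 in the high-survivorship and 9.94, 10.6 and 10.5 in the low-survivorship libraries. Of the 115987 union regions, 35410 (30.5%) were found in all 6 libraries and 29385 (25.3%) in 1 library.

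The best-ranked region held by the low-survivorship population alone lay within NRDE2 (chromosome 14:90288529-90289051), at a mean rank of 906 ± 566 (SD, n = 3) in the low-survivorship and 138226 ± 49433 in the high-survivorship libraries. The log2 rank difference was −7.44 (adjusted p = 3.7e-05). Next came the H2BC3 gene of the histone cluster on chromosome 6, which encodes a histone H2B (6:26043469-26044362, rank 1779 ± 296, SD, n = 3). Its neighbour H3C3, which encodes a histone H3 and is 1 of the 5 best near gene ends, ranked 9525 ± 2145 (6:26045124-26046013). Neither had a peak of any rank in a high-survivorship library (log2 rank difference −6.66 and −4.26, adjusted p = 8.9e-06 and 4.12e-05). After NRDE2 and H2BC3, the other 8 of the 10 best lay near or within NEUROD1, GOLM1, MBD3L1, ZBTB18, NTM, LIMS1, LGR4 and TENM3, at mean ranks of 1971 to 5058. Near gene ends, ZNF141 and LOC124902071 also ranked high in the low-survivorship libraries alone (log2 rank difference −4.68 and −4.65).

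**Figure D1:**
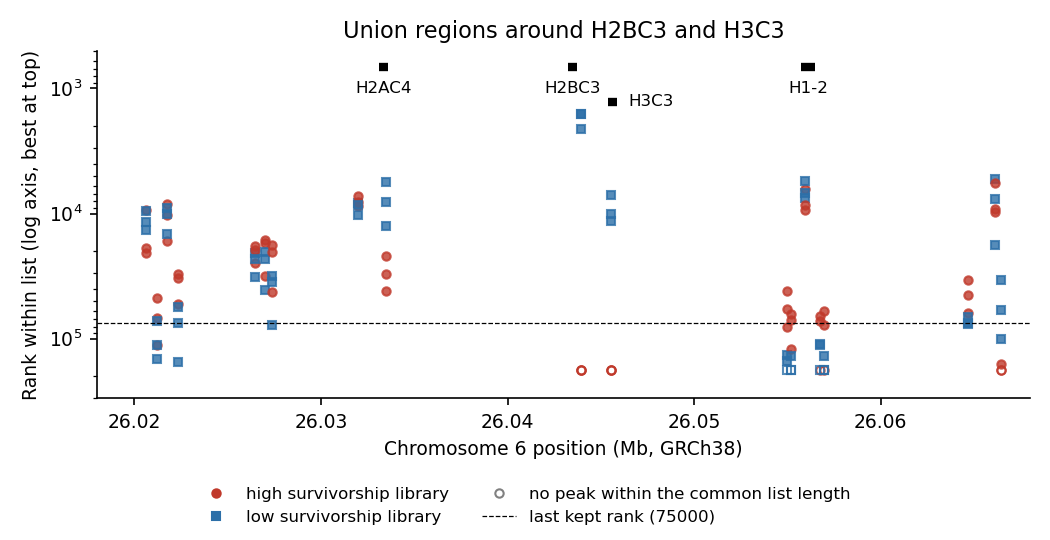
Rank within each list (log axis, best at top) of union regions around H2BC3 and H3C3 against position on chromosome 6 (Mb, GRCh38), 1 point per library and region, with open symbols for libraries with no peak within the common list length and a dashed line at rank 75000. The H2BC3 and H3C3 regions had peaks in the 3 low-survivorship libraries and in 0 high-survivorship libraries.

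Among regions held by the high-survivorship population alone, the best-ranked lay 31260 bp from LOC124903162 (13:40047201-40047843), at a mean rank of 4980 ± 1473 (SD, n = 3) and with no peak of any rank in the low-survivorship libraries (log2 rank difference 5.22, adjusted p = 3.7e-05). A region 10946 bp from SYT6, which encodes a synaptotagmin (1:114164816-114165701), ranked 5245 ± 1352 against 124364 ± 35763 (log2 rank difference 4.56, adjusted p = 4.3e-05). The other 8 of the 10 best lay near or within ELMOD1, FBXL7, ZBBX, LRRC4C, CCDC148, SP100, EPB41L4A and LOC124904304, at mean ranks of 5324 to 6931. Near gene ends the leading regions were those of TUBA3C, which encodes an alpha tubulin, MYL12BP2, NUP62CL, WHRN and ST6GALNAC3, at mean ranks of 8374 to 14309. These 15 regions passed the rank test in every fit that left out 1 library. With normal scores of rank in place of log ranks, NUP62CL did not (adjusted p = 0.064).

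Counted over the genome, 5142 regions were found in 3 of 3 high-survivorship and 0 of 3 low-survivorship libraries, and 5808 the other way round, 10950 in total against at most 1066 in the other 9 splits of the libraries. Regions specific to a population were mostly away from gene ends. Of the high-only and low-only regions, 4.86% and 5.25% lay within 1000 bp of the end of a protein-coding gene. The share was 32.9% among regions found in all 6 libraries and 12.4% among the remaining ones. The share of summits near a gene end also depended on rank. It was 39.6% and 39.2% (high and low survivorship) in the top 25000 and 25.8% in both in the top 75000. Ranks were not matched between these classes. By contrast, 49.9%, 53.6% and 65.3% of the high-only, low-only and all-library regions overlapped a gene, and 53.7% of the remaining ones. The counts depended on how many peaks were kept, with 1661 and 1938 at the top 25000 and 7932 and 12196 with every deposited peak. Where absence meant no peak of any rank in the other population's lists, 1648 and 1828 regions remained, and without high-survivorship library 1 the high-only count was 8205.

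**Figure D2:**
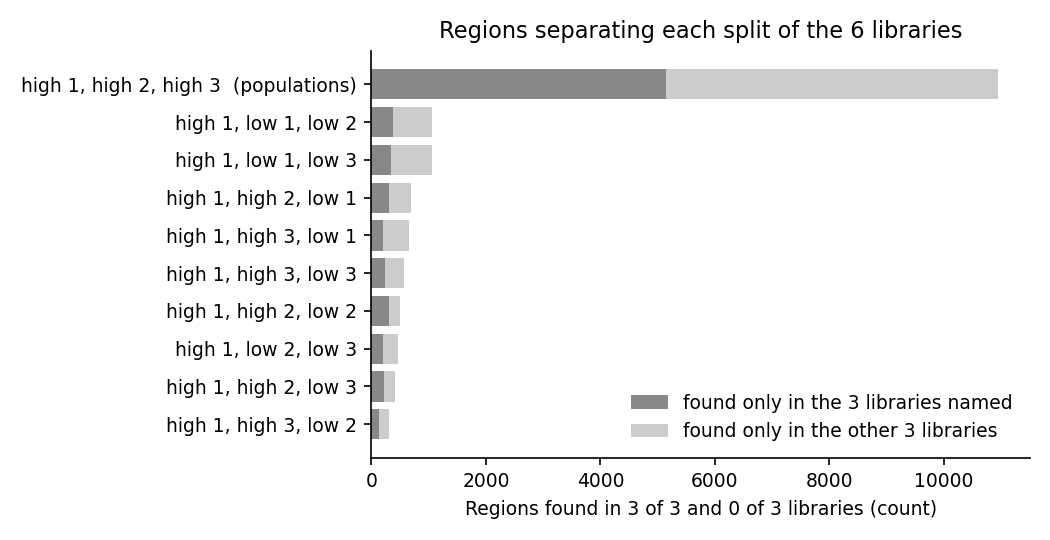
Regions found in 3 of 3 libraries of one side and 0 of 3 of the other (count, horizontal axis) for each of the 10 splits of the 6 libraries, with dark bars for regions of the 3 libraries named and light bars for those of the other 3. The split by population gave 10950 regions and the highest other split 1066.

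The rank test, which also uses regions present in both populations, placed 8111 of 70482 regions higher in the high-survivorship and 9744 higher in the low-survivorship libraries. It called 4696 of the 5142 high-only and 5437 of the 5808 low-only regions. These were chosen from the same ranks, so their calls are not separate support. Among the 35410 regions found in all 6 libraries, 1641 ranked higher in the high-survivorship and 2095 higher in the low-survivorship population, or 2602 and 3018 with the time point as a replicate block. Of the 17855 calls, 12079 were also made in every fit that left out 1 library. Normal scores of rank gave 5177 and 6227 calls.

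At CXCR4, the chemokine receptor for CXCL12 and the marker named with the high-survivorship lists, 6 of 27 assigned regions were specific to the high-survivorship population and 0 to the other. The leading pair lay outside the gene, at 2:136052441-136052770 (rank 11834 ± 2933 against 147506 ± 28106, SD, n = 3, log2 rank difference 3.65, adjusted p = 7.35e-05) and 2:136056286-136056630 (12687 ± 3547 with no low-survivorship peak within the common list length, log2 rank difference 3.86, adjusted p = 5.66e-05). A region within the gene, 2:136116156-136116713, ranked 22613 ± 11548 against 57202 ± 16253 (log2 rank difference 1.41, adjusted p = 0.0228), and the region over the gene end at 2:136117877-136118458 ranked 29365 ± 6870 against 56528 ± 20721 (adjusted p = 0.125). Ranks were better in the low-survivorship libraries at 2:136065783-136065940 and 2:136065977-136066213, by log2 rank differences of −1.54 and −2.08 (adjusted p = 0.0229 and 0.00346). At ITGB2, the integrin beta chain CD18, none of the 5 assigned regions was group-specific and none of the 2 tested passed the rank test, with limma giving adjusted p = 0.149 and 0.385. Whether the sort used these markers is not stated beyond the names of the lists; if it did, regions at their genes are not independent evidence of a difference. The calls at 2:136116156-136116713 and 2:136065783-136065940 each held in 2 of 6 fits that left out 1 library (highest adjusted p = 0.102 and 0.113, without high-survivorship library 2). Normal scores ended the calls at 2:136052441-136052770, 2:136065783-136065940, 2:136057011-136057775 and 2:136119197-136119431 (adjusted p = 0.0602, 0.0802, 0.19 and 0.222).

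**Figure D3:**
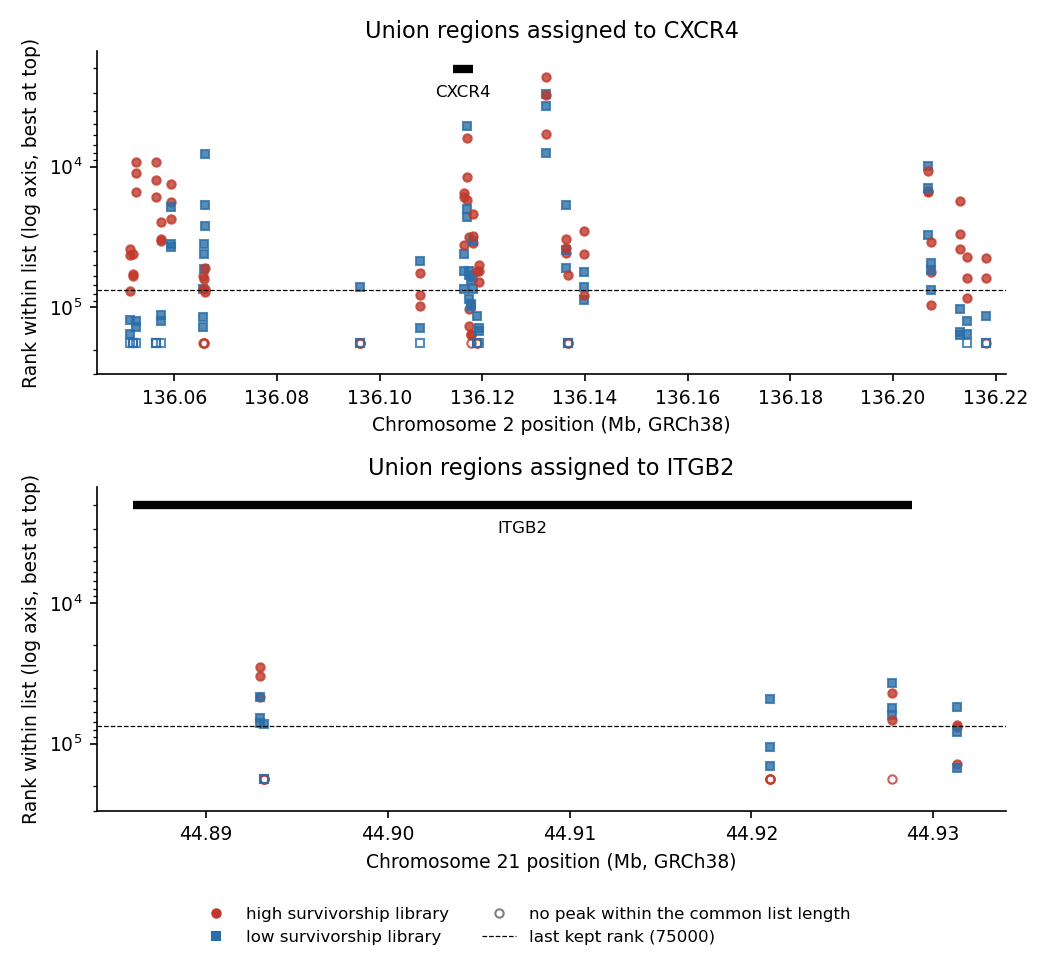
Rank within each list (log axis, best at top) of the union regions assigned to CXCR4 and to ITGB2 against position on chromosomes 2 and 21 (Mb, GRCh38), 1 point per library and region, with open symbols for libraries with no peak within the common list length and a dashed line at rank 75000. Of these, 6 CXCR4 regions and 0 ITGB2 regions were specific to a population.

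Gene lists fixed before the data were examined asked whether group-specific regions gathered at genes of known pathways. None of the 17 lists held more or fewer such genes than matched random lists after adjustment (permutation test, smallest adjusted p = 0.527), while 3 of 34 tests had an unadjusted p under 0.05. These were Wnt signalling with 20 genes against 12.9 ± 2.78 (mean and SD of the random lists) for low-only regions (p = 0.0206), B cell receptor signalling with 22 against 15.7 ± 2.96 for high-only regions (p = 0.0482), and interferon response with 1 against 5.18 ± 2.00 for low-only regions (p = 0.0414), all by permutation. Single regions of most lists did pass the rank test in both directions.

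**Figure D4:**
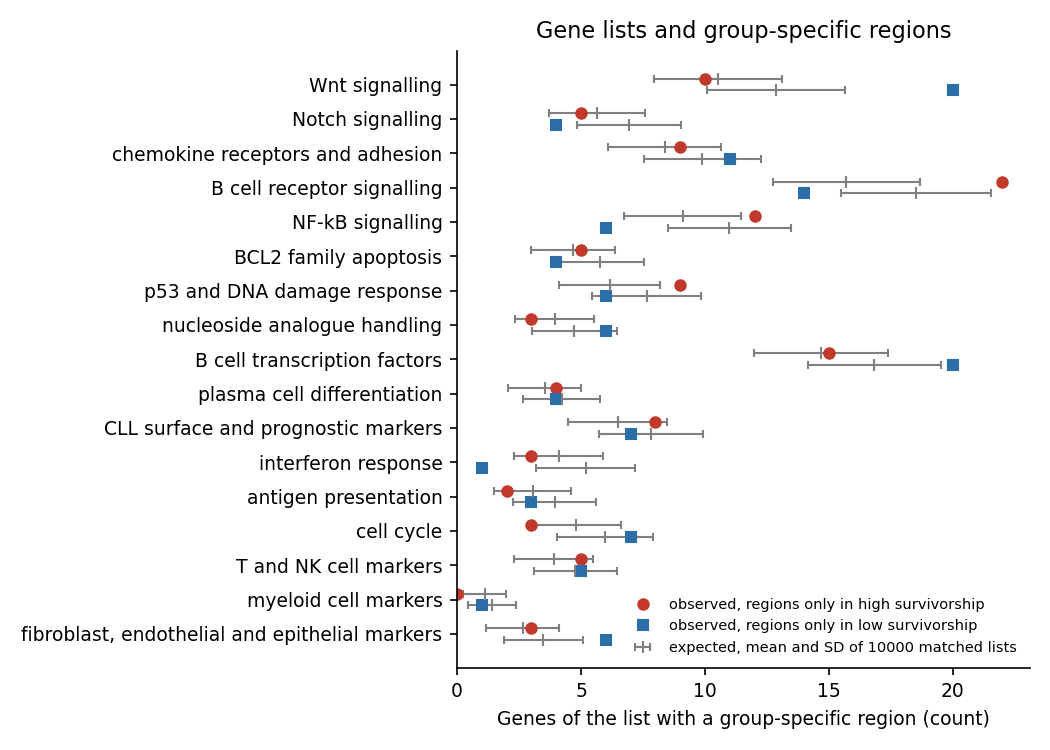
Genes of each list with at least 1 group-specific region (count, horizontal axis), with circles for high-only and squares for low-only regions, beside the mean and SD of 10000 matched random lists in grey. No list lay outside its random lists after adjustment.

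In Wnt signalling, 37 of 237 regions ranked higher in the high-survivorship and 42 higher in the low-survivorship libraries (42 and 47 adjusted over the list alone). High-only regions lay at 10 of the 52 genes with a region, against 10.5 ± 2.59. LGR4, an R-spondin receptor, had a low-only region within the gene (11:27381148-27381433, rank 4968 ± 4677 against 166221 ± 21921, SD, n = 3, log2 rank difference −5.46, adjusted p = 8.05e-05). ROR1, a receptor for WNT5A carried by CLL cells, had one at its gene end (1:63773821-63774271, 16185 ± 3731 against 121887 ± 50198, −2.86, adjusted p = 0.000344), and 9 of its 22 regions ranked higher in the low-survivorship libraries. LGR4 had calls of both directions, 5 of 23 regions ranking higher in the high-survivorship and 3 in the low-survivorship libraries. TLE1, a transcriptional corepressor, had 12 of 38 regions higher in the high-survivorship libraries, the best 92529 bp from the gene (9:81490730-81491153, 8845 ± 3237 with no low-survivorship peak, log2 rank difference 4.40, adjusted p = 4.3e-05). TCF7, a Wnt-responsive transcription factor, had a high-only region within the gene (5:134132255-134132885, 14002 ± 3526 against 143744 ± 37778, 3.35, adjusted p = 0.000133). With normal scores of rank the ROR1 call was lost (adjusted p = 0.126).

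In Notch signalling, 18 of 147 regions ranked higher in the high-survivorship and 8 in the low-survivorship libraries (16 and 8 adjusted over the list alone, 29 and 12 with the replicate block). Of its 33 genes with a region, 5 had high-only and 4 low-only regions, against 5.64 ± 1.94 and 6.93 ± 2.087. MAML2, a Notch coactivator, had regions of both kinds within the gene, high-only at 11:96288956-96289297 (rank 28509 ± 13289 against 102312 ± 18930, SD, n = 3, adjusted p = 0.00315) and low-only at 11:96052775-96053321 (29102 ± 10300, no high-survivorship peak, adjusted p = 0.000367). DTX4 had a high-only region within the gene (11:59174355-59174474, 36061 ± 12810, no low-survivorship peak, adjusted p = 0.000436). RBPJ, the DNA-binding partner of Notch, had regions of both kinds within the gene, high-only at 4:26175443-26175749 (48457 ± 18148 against 170800 ± 13990, adjusted p = 0.00126) and low-only at 4:26126188-26126631 (49834 ± 18738 against 148456 ± 52690, adjusted p = 0.0127). Of its 38 regions, 5 ranked higher in the high-survivorship and 1 in the low-survivorship libraries. The low-only RBPJ call was lost without high-survivorship library 1 or 2 (highest adjusted p = 0.0802) and with normal scores (adjusted p = 0.057).

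Among chemokine receptors and adhesion molecules, 28 of 200 regions ranked higher in the high-survivorship and 26 in the low-survivorship libraries (28 and 26 adjusted over the list alone). Of its 37 genes with a region, 9 had high-only and 11 low-only regions, against 8.37 ± 2.26 and 9.90 ± 2.37. ITGA4, the integrin alpha chain CD49d, had the leading high-only region, 60642 bp from the gene (2:181396137-181396562, rank 14481 ± 328, SD, n = 3, no low-survivorship peak, log2 rank difference 3.63, adjusted p = 5.23e-05). ACKR3, the second receptor for CXCL12, had one within the gene (2:236559624-236559938, 22681 ± 4661 against 163566 ± 14220, 2.87, adjusted p = 0.000216). CD44, the hyaluronan receptor, had a low-only region within the gene (11:35182272-35182678, 22254 ± 2720 against 149498 ± 35315, −2.73, adjusted p = 0.0003). CCR6 had one 8601 bp away (6:167103043-167103193, 43032 ± 7945 against 135587 ± 38112, −1.64, adjusted p = 0.00442). Calls higher in the high-survivorship and in the low-survivorship libraries numbered 4 and 3 at ITGA4, 2 and 1 at ACKR3, 1 and 3 at CD44 and 2 and 3 at CCR6. Normal scores ended the calls of ACKR3, CD44 and CCR6 (adjusted p = 0.0959, 0.12 and 0.265).

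In B cell receptor signalling, 62 of 390 regions ranked higher in the high-survivorship and 47 in the low-survivorship libraries (63 and 49 adjusted over the list alone). High-only regions numbered 39 and low-only regions 23, 62.9% high-only against 45.0% over all assigned regions (exact binomial p = 0.00492, adjusted p = 0.0836 over the lists). Low-only regions lay at 14 of the 48 genes, against 18.5 ± 3.02. PIK3R5, a regulatory subunit of phosphoinositide 3-kinase gamma, had 7 high-only regions among 21, the best within the gene (17:8939908-8940245, rank 22593 ± 7835 against 176041 ± 4913, SD, n = 3, log2 rank difference 3.02, adjusted p = 0.000236). RASGRP1, a Ras activator, had a high-only region 66261 bp away (15:38631076-38631866, 22494 ± 10669 against 118342 ± 41918, 2.46, adjusted p = 0.00116). Low-only regions lay near PIK3R1, a regulatory subunit of class I phosphoinositide 3-kinases (5:68196956-68197250, 23444 ± 6110, −2.96, adjusted p = 0.000197), and within NFATC1 (18:79438467-79438706, 33168 ± 10479, −2.48, adjusted p = 0.000402), neither with a high-survivorship peak. Over all its 26 regions PIK3R1 had 4 calls higher in the high-survivorship and 1 higher in the low-survivorship libraries, against 2 and 5 at NFATC1 and 2 and 1 at RASGRP1.

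In NF-kB signalling, 33 of 250 regions ranked higher in the high-survivorship and 19 in the low-survivorship libraries (29 and 16 adjusted over the list alone). Of its 40 genes with a region, 12 had high-only and 6 low-only regions, against 9.10 ± 2.37 and 10.99 ± 2.49. TNFAIP3, an inhibitor of NF-kB, had both a high-only region within the gene (6:137873305-137873728, rank 28715 ± 8478 against 79853 ± 8275, SD, n = 3, adjusted p = 0.00658) and a low-only region 18889 bp away (6:137846832-137847459, 33699 ± 17596 against 162097 ± 29064, adjusted p = 0.00114). NFKB1 had a high-only region (4:102535927-102536066, 36249 ± 13515, no low-survivorship peak, adjusted p = 0.000474) and TNFAIP8 a low-only one (5:119356467-119356590, 35584 ± 14109 against 141736 ± 38275, adjusted p = 0.00228), which normal scores did not call (adjusted p = 0.207). In these genes calls went both ways, 7 higher in the high-survivorship and 4 in the low-survivorship libraries at TNFAIP3, 3 and 1 at NFKB1 and 3 and 4 at TNFAIP8.

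Of the BCL2 family, which governs mitochondrial apoptosis, 13 of 135 regions ranked higher in the high-survivorship and 5 in the low-survivorship libraries (13 and 4 adjusted over the list alone, 18 and 12 with the replicate block). Of its 19 genes with a region, 5 had high-only and 4 low-only regions, against 4.69 ± 1.69 and 5.75 ± 1.77. PMAIP1, which encodes the proapoptotic protein NOXA, had the leading high-only region 48686 bp away (18:59952992-59953349, rank 19444 ± 4470 against 160865 ± 31198, SD, n = 3, log2 rank difference 3.06, adjusted p = 0.000191). BCL2 itself had one within the gene (18:63158956-63159233, 24950 ± 6539 against 154754 ± 41782, 2.63, adjusted p = 0.000423). Of all regions of PMAIP1 and BCL2, 4 and 4 ranked higher in the high-survivorship and 1 and 2 in the low-survivorship libraries. The low-only regions had poorer ranks, near PMAIP1 (18:59971135-59971464, 55381 ± 13088 against 114758 ± 30246, −1.05, adjusted p = 0.0483) and BCL2L10 (15:52104517-52104648, 57442 ± 13886 against 127187 ± 51537, adjusted p = 0.0581, or 0.0144 with the time point as a replicate block). The low-only PMAIP1 call was lost in all 6 fits that left out 1 library (highest adjusted p = 0.146, without high-survivorship library 1) and with normal scores (adjusted p = 0.23). It was also lost when regions of any library were tested and with plain empirical Bayes (adjusted p = 0.0702 and 0.0541).

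In the p53 and DNA damage response, 21 of 161 regions ranked higher in the high-survivorship and 13 in the low-survivorship libraries (18 and 13 adjusted over the list alone). Of its 33 genes with a region, 9 had high-only and 6 low-only regions, against 6.15 ± 2.03 and 7.65 ± 2.19. PHLDA3, a p53 target that inhibits AKT, had a high-only region at its gene end (1:201468435-201469748, rank 15463 ± 6803, SD, n = 3, no low-survivorship peak, log2 rank difference 3.63, adjusted p = 0.00013). TP53INP1, another p53 target, had one within the gene (8:94947187-94947397, 25892 ± 5908 against 120827 ± 52546, 2.16, adjusted p = 0.00157). Low-only regions lay within BRCA2, a gene of homologous recombination (13:32354145-32354398, 39983 ± 15714 against 120288 ± 41236, −1.62, adjusted p = 0.0145), and near GADD45G (9:89562424-89562831, 41167 ± 11701 against 129091 ± 46122, −1.63, adjusted p = 0.00943). GADD45G also had a high-only region 94744 bp away (9:89701300-89701856, 26363 ± 11344 against 132088 ± 49369, 2.36, adjusted p = 0.00181), and 2 of its 12 regions ranked higher in each population. Without high-survivorship library 2 the adjusted p of the BRCA2 and GADD45G regions was 0.0725 and 0.0506, and the BRCA2 call was also lost without low-survivorship library 1. Normal scores called neither of these low-only regions, nor those of TP53INP1 and the high-only one of GADD45G (adjusted p = 0.082, 0.272, 0.196 and 0.172).

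Genes that handle nucleoside analogues, the class of fludarabine, had 10 of 90 regions ranking higher in the high-survivorship and 16 in the low-survivorship libraries (11 and 17 adjusted over the list alone). Of its 21 genes with a region, 3 had high-only and 6 low-only regions, against 3.93 ± 1.60 and 4.73 ± 1.72. High-only regions lay within the transporter genes ABCB1 (7:87598278-87598502, rank 16322 ± 6888 against 120784 ± 50832, SD, n = 3, log2 rank difference 2.92, adjusted p = 0.000481) and ABCC4 (13:95260042-95260549, 40841 ± 11297 against 160755 ± 19014, 2.01, adjusted p = 0.000905). Low-only regions lay within NT5E, the ecto-nucleotidase CD73 (6:85465843-85466068, 24666 ± 7923 against 119522 ± 33749, −2.29, adjusted p = 0.000937), and 1162 bp from RRM2, a subunit of ribonucleotide reductase (2:10121260-10121405, 38684 ± 7484 against 166914 ± 20720, −2.12, adjusted p = 0.000513). ABCC4 had a low-only region as well (13:95251083-95251330, 54622 ± 9454 against 140066 ± 37976, −1.34, adjusted p = 0.00868), and 5 of its 22 regions ranked higher in the low-survivorship and 1 in the high-survivorship libraries, against 1 and 5 of 14 at ABCB1. The ABCB1 call and both ABCC4 calls were lost with normal scores (adjusted p = 0.126, 0.164 and 0.301), and the low-only ABCC4 call without high-survivorship library 3 (adjusted p = 0.0716).

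The list of B cell transcription factors held the largest number of tested regions, 449, of which 58 ranked higher in the high-survivorship and 84 in the low-survivorship libraries (63 and 87 adjusted over the list alone). Of its 35 genes with a region, 15 had high-only and 20 low-only regions, against 14.7 ± 2.70 and 16.8 ± 2.70. Both kinds lay at 13 of the genes. EBF1, which commits progenitors to the B lineage, had a low-only region within the gene at 5:158995471-158996070 (rank 8528 ± 3943 against 124731 ± 10558, SD, n = 3, log2 rank difference −4.00, adjusted p = 0.000108) and a high-only one at 5:158911226-158911606 (29980 ± 4437 against 113672 ± 56503, 1.83, adjusted p = 0.00461). TOX had a low-only region within the gene (8:59044205-59044445, 9637 ± 2216 against 162548 ± 28283, −4.09, adjusted p = 4.55e-05). BCL6, a transcriptional repressor required for germinal centres, had a high-only region 57353 bp away (3:187802822-187803297, 20601 ± 5535 against 162840 ± 27777, 3.01, adjusted p = 0.000231). Of 64 EBF1 regions, 10 ranked higher in the high-survivorship and 4 in the low-survivorship libraries, and of 15 TOX regions 2 and 5. The high-only EBF1 call was lost with normal scores (adjusted p = 0.242).

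In the plasma cell list, 14 of 83 regions ranked higher in the high-survivorship and 10 in the low-survivorship libraries (15 and 11 adjusted over the list alone). Of its 14 genes with a region, 4 had high-only and 4 low-only regions, against 3.53 ± 1.48 and 4.21 ± 1.55. CD38, an ectoenzyme used as a prognostic marker in CLL, had a low-only region within the gene (4:15806189-15806511, rank 14883 ± 5234 against 152996 ± 23173, SD, n = 3, log2 rank difference −3.42, adjusted p = 0.000142). SEL1L had one near the gene (14:81535955-81536139, 21677 ± 4049 against 147292 ± 54707, −2.70, adjusted p = 0.000437). ELL2, an elongation factor, had a high-only region 854 bp outside the gene (5:95883425-95884243, 30335 ± 5360 against 134452 ± 31016, 2.13, adjusted p = 0.000821). That at CD27 did not pass (12:6443464-6443935, 59046 ± 5559 against 110909 ± 31759, adjusted p = 0.0806). At CD38, SEL1L and ELL2, 2, 2 and 5 regions ranked higher in the high-survivorship and 3, 2 and 1 in the low-survivorship libraries. Normal scores ended the CD38 and SEL1L calls (adjusted p = 0.071 and 0.0561).

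Among CLL surface and prognostic markers, 27 of 148 regions ranked higher in the high-survivorship and 16 in the low-survivorship libraries (27 and 17 adjusted over the list alone). Of its 28 genes with a region, 8 had high-only and 7 low-only regions, against 6.48 ± 1.99 and 7.81 ± 2.092. ITGA4, described above with the adhesion molecules, belongs to both lists. CD274, the ligand PD-L1, had a high-only region 9470 bp away (9:5480025-5480280, rank 26984 ± 9387 against 114913 ± 32956, SD, n = 3, log2 rank difference 2.12, adjusted p = 0.00166) and a low-only one within the gene (9:5451550-5451786, 43757 ± 10933 against 99628 ± 31744, −1.18, adjusted p = 0.0417). LPL, a lipase whose expression marks unfavourable CLL, had a low-only region (8:19962256-19962634, 43540 ± 7206, no high-survivorship peak, −2.05, adjusted p = 0.000396). The low-only CD274 call was lost in all 6 fits that left out 1 library (highest adjusted p = 0.153, without low-survivorship library 2) and with normal scores (adjusted p = 0.102).

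Interferon response genes had few differing regions, 4 of 105 higher in the high-survivorship and 7 in the low-survivorship libraries (2 and 4 adjusted over the list alone, 9 and 11 with the replicate block), with high-only regions at 3 of 40 genes against 4.10 ± 1.81. IFIT5 had a high-only region that passed (10:89419685-89419878, 54147 ± 5234 against 160597 ± 31661, SD, n = 3, adjusted p = 0.00148). ISG20 had the single low-only region of the list (15:88683392-88683658, 26328 ± 2649 against 97419 ± 4905, adjusted p = 0.000959). Antigen presentation genes had 2 of 96 regions higher in the high-survivorship and 6 in the low-survivorship libraries (1 and 1 adjusted over the list alone, 5 and 7 with the replicate block). Of its 20 genes with a region, 2 had high-only and 3 low-only regions, against 3.04 ± 1.55 and 3.94 ± 1.67. The best were 20639 bp from HLA-B for the high-survivorship (6:31332706-31333235, 23255 ± 5878 against 164239 ± 25354, adjusted p = 0.000286) and near HLA-DOA and within CIITA, the class II transactivator, for the low-survivorship libraries (6:33018877-33019274, 41202 ± 12497 against 97610 ± 31411, adjusted p = 0.0358, and 16:10878451-10878715, 55796 ± 1831 against 166217 ± 21928, adjusted p = 0.000777). The HLA-DOA call held in 1 of 6 fits that left out 1 library (highest adjusted p = 0.147, without low-survivorship library 2) and was lost with normal scores (adjusted p = 0.0848).

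Cell cycle genes had 14 of 167 regions higher in the high-survivorship and 20 in the low-survivorship libraries (14 and 20 adjusted over the list alone). Of its 32 genes with a region, 3 had high-only and 7 low-only regions, against 4.80 ± 1.82 and 5.95 ± 1.94. CDK6, a kinase of the G1 phase, had a high-only region (7:92708683-92708979, rank 20532 ± 3110 against 145549 ± 57726, SD, n = 3, log2 rank difference 2.74, adjusted p = 0.000436) and a low-only one (7:92748581-92748841, 35526 ± 18266 against 128740 ± 45818, −1.93, adjusted p = 0.00697), both within the gene. Of its 49 regions, 10 ranked higher in the high-survivorship and 5 in the low-survivorship libraries. CDKN2A, which encodes an inhibitor of CDK4 and CDK6, had a low-only region within the gene (9:21986393-21986598, 36257 ± 13137, no high-survivorship peak, −2.37, adjusted p = 0.000497). Both CDK6 calls were lost with normal scores (adjusted p = 0.0627 and 0.234).

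Markers of other cell types also had regions on both sides. In the T and NK cell list, 11 of 74 regions ranked higher in the high-survivorship and 10 in the low-survivorship libraries (12 and 11 adjusted over the list alone). Of its 21 genes with a region, 5 had high-only and 5 low-only regions, against 3.90 ± 1.59 and 4.77 ± 1.69. The best lay near PRF1 for the high-survivorship (10:70587276-70587588, rank 32347 ± 11512, SD, n = 3, adjusted p = 0.000456) and near GZMB for the low-survivorship population (14:24699078-24699391, 17836 ± 7254, adjusted p = 0.000181), neither with a peak in the other population. Of the 21 tested regions of the myeloid list, 7 ranked higher in the low-survivorship and 0 in the high-survivorship libraries (7 and 0 adjusted over the list alone, 7 and 2 with the replicate block). The 7 lay at CD68, CSF1R, VCAN and MS4A7. Group-specific regions lay at 1 of 16 myeloid genes, MS4A7 (11:60377728-60378018, 60530 ± 8756 against 153804 ± 43428, adjusted p = 0.00702), against 1.40 ± 0.979 for low-only and 1.11 ± 0.879 for high-only regions. That call was lost without high-survivorship library 2 or 3 (highest adjusted p = 0.0665). Fibroblast, endothelial and epithelial markers had 4 of 52 regions higher in the high-survivorship and 9 in the low-survivorship libraries (4 and 9 adjusted over the list alone). Of its 18 genes with a region, 3 had high-only and 6 low-only regions, against 2.65 ± 1.47 and 3.47 ± 1.60. The best were within CDH1 (16:68782705-68783139, 48856 ± 16634 against 175952 ± 5067, adjusted p = 0.00072) and, for the low-survivorship population, near COL3A1 (2:188919833-188920220, 21377 ± 9599 against 133810 ± 30443, adjusted p = 0.000493). COL3A1 had 1 call in each direction.

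Libraries of the same population shared more of their open chromatin than libraries of different populations. The mean Jaccard index was 0.635 ± 0.0272 (SD over 6 pairs) within and 0.517 ± 0.0192 (9 pairs) between populations, a difference of 0.118. No other split of the libraries exceeded a difference of 0.0041 (exact permutation test over 10 splits, one-sided p = 0.1, the smallest it can give). Between populations, pairs of the same time point had an index of 0.53 and other pairs 0.51.

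The share of kept summits within 1000 bp of the end of a protein-coding gene was 25.8% ± 0.718 (SD, n = 3) in the high-survivorship and 25.8% ± 0.687 in the low-survivorship libraries. The difference, −0.0582 percentage points, was smaller than the SD within either population (exact permutation test, two-sided p = 0.5). The share was lower in the high-survivorship library at each of the 3 time points, and exchanging labels only within time points gave an exact p of 0.25, the smallest it can give. With the top 25000 the difference was 0.483, within 2500 bp 0.236 and with every deposited peak −1.09 percentage points. It also turned positive without high-survivorship library 2 or 3 or low-survivorship library 1 (0.122, 0.176 and 0.338).

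Group-specific regions were spread over the chromosomes unevenly, with 9 combinations of chromosome and direction above and 9 below expectation after adjustment. Chromosome 13 held the largest excess, with 7.05% of its union regions low-only against 4.96% elsewhere (ratio 1.42, adjusted p = 1.32e-05, Fisher's exact test). It was followed by chromosome 14 with 5.59% high-only against 4.40% elsewhere (ratio 1.27, adjusted p = 0.00335) and chromosome 4 with 6.21% low-only against 4.92% (ratio 1.26, adjusted p = 1.06e-05). The other excesses were chromosomes 3 and 4 for high-only and chromosomes 2, 6, 7 and 18 for low-only regions, at ratios of 1.13 to 1.25. Chromosomes 17, 19 and 22 lay below expectation in both directions, with ratios of 0.619, 0.494 and 0.429 for high-only and 0.568, 0.367 and 0.365 for low-only regions. Chromosome 20 was below for high-only regions (0.704), and chromosomes 1 and 16 for low-only regions (0.769 and 0.691). Among regions farther than 1000 bp from a gene end, an added test, 5 combinations were above and 8 below expectation, and 6 and 13 were above with the top 25000 and the top 100000. The excess of chromosome 14 was absent with the top 25000 (ratio 0.958, adjusted p = 0.846). Of the low-only excesses, that of chromosome 2 was lost without low-survivorship library 1 (adjusted p = 0.131) and that of chromosome 18 away from gene ends (adjusted p = 0.185). Chromosome 6 did not pass without high-survivorship library 3 or low-survivorship library 2 (highest adjusted p = 0.103), with the top 25000 (adjusted p = 0.815) or away from gene ends (adjusted p = 0.205). Chromosome 7 did not pass without high-survivorship library 1 or 3 or low-survivorship library 1 (highest adjusted p = 0.174), with the top 25000 (ratio 0.963, adjusted p = 0.815) or top 100000 (adjusted p = 0.342), or away from gene ends (adjusted p = 0.217). The high-only excess of chromosome 4 was lost without high-survivorship library 1 or low-survivorship library 2 or 3 (highest adjusted p = 0.597), with the top 25000 (adjusted p = 0.281) and away from gene ends (adjusted p = 0.455). Without high-survivorship library 1, the high-only deficits of chromosomes 20 and 22 did not pass (adjusted p = 0.355 and 0.14), nor did chromosome 20 away from gene ends (adjusted p = 0.0728) or chromosome 22 with the top 25000 (adjusted p = 0.0593). In all settings of this test, the excesses of chromosomes 4 and 13 (low-only) and 3 (high-only) passed, as did the other 7 deficits. Set directly against each other, an added test, high-only and low-only regions differed in balance from the other chromosomes on chromosomes 1 (444 and 401, adjusted p = 0.017) and 14 (200 and 165, adjusted p = 0.027). No difference in balance was called on the others, with chromosome 13 at 143 and 194 (adjusted p = 0.3) and chromosome 4 at 380 and 465 (adjusted p = 0.363), so an excess of one kind there is not shown to differ between the populations. Regions of 1 chromosome are not independent of each other, which these p-values ignore.

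With 1 library per population and time point, time could not be tested within a population. In each pair of time points, more regions separated the populations than the time points. Time points 1 and 2 differed at 4330 regions in both populations alike, while 17069 regions separated the populations in the same 4 libraries, a ratio of 3.94. The ratio was 3.63 for time points 1 and 3 (16325 against 4493) and 6.36 for time points 2 and 3 (18390 against 2890). With every deposited peak the last ratio was 4.09. The remaining split of each 4 libraries, which crosses population and time point, gave 1988 regions for time points 1 and 2. It gave 2124 for time points 1 and 3 and 1997 for 2 and 3. Not all of the 4330, 4493 and 2890 regions can therefore be put down to time.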

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

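Settings chosen after the data were seen were the chromosome test away from gene ends, the gene list tests without each library, the lists on regions absent from whole deposited lists and the lists on rank calls. More regions separated the populations than any other split of the libraries under each number of peaks kept, presence rule and window tested. With the top 25000, 1661 high-only and 1938 low-only regions were found, and with every deposited peak 7932 and 12196. Requiring −log10 q of at least 2 removed no peak and so gave the same 7932 and 12196. Absence from whole lists, a stricter rule by construction, gave 1648 and 1828. Leaving out 1 library or 1 time point, which loosens the rule, gave 5790 to 9117 high-only and 6612 to 9273 low-only regions. The rank test gave 5177 and 6227 calls with normal scores of rank, for which the cause was not tested. It gave 1381 and 1867 among regions of all 6 libraries and 2185 and 2819 among regions in the top 25000 of at least 3 libraries, where fewer regions were tested. The fit with a replicate block by time point gave 10190 and 11865, ended no call of a named region, gave a call to 4, and moved no count of list calls by over 1.5 times beyond those given with it above. The difference in gene-end share turned positive with the top 25000 (0.483 percentage points) and within 2500 bp (0.236), was −1.09 with every deposited peak, and ran from −0.472 to 0.338 without 1 library, none past an exact test; the cause was not tested. Combinations of chromosome and direction above expectation numbered 5 away from gene ends. The ratio for time points 2 and 3 was 4.09 with every deposited peak. The cause of these changes was not tested. No gene list passed in any of its alternatives (smallest adjusted p = 0.201).

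Of 166 named regions tested, 144 were called, and 119 of these kept the call without each library in turn. Normal scores ended 52 of the calls, plain empirical Bayes 4 and a test of regions of at least 1 library 6. Among CXCR4 regions without a call, normal scores turned 2:136065382-136065721 (to −1.0) and 2:136207156-136207654 (to −0.0185). Without 1 library, log2 rank differences ran from −0.124 to 0.662 at 2:136065382-136065721, −0.113 to 0.973 at 2:136116829-136117322, −0.847 to 0.208 at 2:136117380-136117610 and −0.0417 to 0.755 at 2:136131991-136132655. They ran from −0.442 to 0.301 at 2:136136216-136136466, −0.187 to 0.619 at 2:136206520-136207031 and −0.330 to 0.414 at 2:136207156-136207654, and the cause of these turns was not tested. The planned motif search was not run, for want of a genome sequence. With no read counts, the depth of the libraries is unknown, and so is the smallest difference that each list could show.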

Other observations

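The tests of this part were chosen after the results were seen, the counts over other splits of the libraries apart, whose bound was also written afterwards. Some genes held many group-specific regions of a single direction: 23 genes had more high-only and 18 more low-only regions than expected from their union regions, of 16770 genes tested, and 0 had both (hypergeometric test). OPCML, a cell adhesion molecule of the immunoglobulin superfamily, led the high-only genes with 21 of 57 regions (adjusted p = 3.8e-11), followed by RBFOX1, an RNA-binding splicing regulator, with 18 of 51 and ROBO2, an axon guidance receptor, with 27 of 129. OPCML, RBFOX1 and ROBO2 also had 2, 1 and 1 low-only regions. FBXL7 and CTNNA2, an alpha catenin, had 9 of 18 and 11 of 32. Among low-only genes, ITGA9, an integrin alpha chain, had 11 of 27 (adjusted p = 9.66e-05), TENM3 14 of 51, FAT1 9 of 24 and the homeobox gene MEIS1 5 of 7. TENM3 also had 3 high-only regions. FOXP1, a transcription factor of B cell development, had 10 of 36 (adjusted p = 0.00725), and ROR1 had 7 of 22 (adjusted p = 0.0441).

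In every test without 1 library, 12 genes of each direction passed, among them OPCML, RBFOX1, ROBO2, FBXL7, CTNNA2, ITGA9, TENM3, FAT1, MEIS1 and FOXP1 but not ROR1. For regions absent from whole lists of the other population, 17 high-only and 5 low-only genes passed, 10 and 4 of them shared with the genes above. Regions of a gene are not independent, which these p-values ignore. Several of these genes lie in the segments described below and are not separate observations. OPCML lies in 11:132000001-134000000 (22 of 84 regions high-only) and ROBO2 largely in 3:76000001-78000000 (27 of 133). The question of DNA copy raised there is open for such genes as well. A peak-free gap of 895 kb lay in 13q14 in all 6 libraries (13:49997625-50892253), with KCNRG and DLEU7 inside. Longer gaps without a peak in any library lay elsewhere, such as X:7996707-9807527 (1811 kb, 7 protein-coding genes). These gaps were not matched to the one in 13q14 by chromosome, sequence or gene content. Whether its length was exceptional, and its cause, were therefore not tested.

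The populations were separated by 10950 group-specific regions and 17855 rank calls, against at most 1066 and 0 in the other 9 splits, which had 445 to 3412 regions at an unadjusted p under 0.05 by limma against 24114. In 1 and 1 of the 10 splits, the real one, were the counts this large, and 10 splits are too few for a share under 0.05. The other 3 splits that part all time-point pairs gave 405, 312 and 459 regions. Every other split mixes libraries of both populations, so a population difference widens the spread within its sides. Low counts in those splits are therefore no measure of noise alone. Scatter of ranks around the last kept one is argued against by the 3476 regions with no peak of any rank in the other population, against 15 in the highest other split. Depth is unknown. Such regions occurred in both directions (1648 high-only and 1828 low-only). Every list was limited to 300000 peaks, so a difference in depth could also leave absences in both directions. These counts therefore do not decide on depth. A difference between the sorted populations stays open as a hypothesis.

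Group-specific regions of one direction gathered in segments of 2 Mb, 58 with an excess of high-only and 39 of low-only regions among 1460, led by 8:136000001-138000000 with 31 of 64 and 4:186000001-188000000, which holds FAT1, with 21 of 82. Loss of a DNA copy in the other population could lower all regions of a segment. Strong regions there (geometric mean rank up to 20000) had a median log2 rank difference of 0.0314 (95% interval −0.0624 to 0.140) in the high-only and −0.171 (−0.363 to −0.0203) in the low-only segments, against 2.07 and −2.001 for the group-specific ones and 0.0894 elsewhere. The intervals come from 2000 resamples of single regions, not of libraries or segments, so they do not measure the spread between samples. Strong regions were chosen by their rank over both populations, which leaves out regions that fell far in one. How far a lost copy moves a rank is not known here. Copy loss and closed chromatin therefore cannot be told apart for these segments as a set. Not every region moved with the excess, however. Of the strong regions in the high-only and low-only segments, 8.33% and 7.72% were called the other way. Rank calls higher in the high-survivorship and low-survivorship libraries numbered 35 and 0 at 8:136000001-138000000, but 23 and 16 at 7:46000001-48000000.

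In 14 stretches on 10 chromosomes, all high-survivorship libraries had regions (92 in total) where no low-survivorship library had a peak of any rank. They included 9:23089701-24053323 with ELAVL2, 2:80073222-80519911 within CTNNA2, 16:5634119-6682264 within RBFOX1 and 19:22053586-23116761 with ZNF98, ZNF492, ZNF99 and ZNF723. The reverse held for 1 stretch, 2:192711890-192724318, and the other splits gave 0. Loss of both DNA copies in the low-survivorship population and closed chromatin cannot be told apart, since the stretches were chosen for having 0 peaks there. The same is open for H2BC3 and H3C3, with 0 peak lines from one region to the other in the high-survivorship libraries against 36 (12, 13 and 11) in the low-survivorship ones, over a span of 2545 bp, because lost copies of this segment and closed chromatin would both leave 0.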
